A study of Mus musculus with 24 samples.

How the data were processed

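RNA from brain microglia of mice was sequenced in 24 libraries, in 8 groups of 3. Microglia had been sorted by flow cytometry as cells with intermediate CD45 and positive CD11b. The mice carried Dicer1 alleles that tamoxifen-activated Cre recombinase deletes. Cre+ mice had the recombinase (creERT2) at the Cx3cr1 locus and Cre- mice lacked it. Each genotype was sampled in 4 states: naive; demyelination by the copper chelator cuprizone; and remyelination on normal diet after cuprizone, in separate groups by tamoxifen timing. Tamoxifen was given at the start in the naive, demyelination and first remyelination groups, and at the peak, in week 5 of cuprizone, in the other remyelination group. The series text describes the 3 samples of each group as biological replicates, so the p values measure the spread between these samples; the labels do not number the animals.

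Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to GRCm38 with STAR 2.5.2b and counted per gene with featureCounts of Subread 1.5.2, and DESeq2 was used for normalisation and testing. The deposited table holds raw counts per Ensembl gene, and those counts were the input here. The strand setting and the handling of multimapping reads are not given in the sources used here, so values of overlapping or antisense genes and of near-identical copies (Hspa1a and Hspa1b, class I H2 genes, Ifit3 and Ifit3b) are uncertain. Of 49315 gene identifiers, 49056 matched the GENCODE M21 annotation of GRCm38, which gave symbols and positions, and 259 did not.

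Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups, which left 17579 genes. Libraries were scaled by TMM, group means were fitted to all 24 libraries together with robust quasi-likelihood dispersions (16 residual degrees of freedom), and contrasts were tested by the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes past it are called higher or lower. CPM are counts per M counts (M for mega) and use TMM-scaled library sizes. Standard errors are those of the fitted log2 fold changes. The 12 comparisons were: Cre+ minus Cre- in each of the 4 states; the difference of that effect between demyelination and naive, between remyelination (tamoxifen at the start) and demyelination, and between both tamoxifen timings; demyelination minus naive within each genotype; and 3 comparisons of remyelination states within Cre- mice. Each genotype comparison has its own Cre- libraries.

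Gene lists were written before the data were examined, as were the comparisons, the thresholds, the rule for naming genes and all alternatives except those named below as added. There were 30 lists. Of these, 18 concern programmes: homeostatic microglia, disease-associated microglia, interferon response, MHC class II, MHC class I, inflammatory cytokines and chemokines, cell cycle, p53 targets, cholesterol biosynthesis, lipid efflux and storage, phagocytosis receptors and complement, lysosome, growth factors, TGF-beta signalling, miRNA machinery other than Dicer1, let-7 targets, miR-155 and miR-146a targets, and dissociation and immediate early genes. Another 12 hold miRNA host genes and markers of border-associated macrophages, monocytes, neutrophils, T, NK and B cells, oligodendrocytes, oligodendrocyte precursors, astrocytes, neurons, endothelial cells, mural cells and erythroid cells. Each list was tested with camera of limma 3.58.1 (preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison), and again with an estimated correlation and with fry. Seed-site tests asked with camera whether genes with a site for an miRNA family in the 3′ UTR (at least 50 bases) shifted against other genes, for 21 families expressed in microglia and 3 control families.

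Named genes are Dicer1 and Cx3cr1; in each comparison, the 8 called genes with the largest rise and the 8 with the largest fall among those with an official symbol, a mean log2 CPM of at least 2 and no overlap between groups (no overlap rule for interactions), called eligible genes; and up to 4 members with the smallest p from each list. Sex-linked, erythroid and immunoglobulin genes were left out of the first rule. All 24 libraries had the expression pattern of males (Xist counts of 0 to 9, Ddx3y counts of at least 939), so sex was not used as a covariate. Whether replicate numbers pair samples was checked from correlations of residuals: with tamoxifen at the peak, each of the 3 Cre+ libraries correlated best with the Cre- library of its own number (r across genes 0.16 to 0.23), and a replicate block was fitted there and elsewhere as an alternative.

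The procedure was tested on simulated data with the library sizes of the naive and of the start-tamoxifen groups. The spread of each gene was its single dispersion across all 24 libraries, not that of these groups alone. Genes set to change were drawn from those with a log2 CPM above 2. Of these, edgeR recovered 56.7% and 49.3% at 1.5-fold, 89.6% and 85.1% at 2-fold, and 98.5% at 4-fold in each. Of the calls, 9 of 190 and 11 of 183 were false. Within groups, log2 CPM of library pairs correlated across genes with Pearson r of 0.9714 to 0.9903.

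Alternatives written before the data were examined were DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in 3 libraries, fitting only the groups compared, the replicate block, DESeq2 1.42.0, limma-voom with sample quality weights, a 2-fold minimum, and leaving out each library in turn. Those added after seeing the data were a correction for GC content and transcript length and leaving out 3 Cre+ libraries with very low Cx3cr1. Reads were not realigned, so excision of the Dicer1 exon was not examined, and protein, miRNA and single-cell data were not analysed here.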

Results

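The data are gene-level counts from 24 libraries, 3 Cre+ and 3 Cre- in each of 4 states. Totals were 19.48 to 44.53 M counts in naive and 21.87 to 32.71 M in demyelination libraries. They were lower in remyelination, 8.87 to 12.56 M with tamoxifen at the start and 8.94 to 12.09 M with tamoxifen at the peak. The first principal component of the 1000 most variable genes (43.4% of variance) separated the 12 remyelination libraries from the 12 naive and demyelination libraries. The second (34.1%) separated demyelination from naive. Genome positions are those of GRCm38.

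Dicer1 (ENSMUSG00000041415, chromosome 12, 104687742 to 104751952) encodes the ribonuclease that cuts miRNA precursors into mature miRNAs. Its summed exon counts were not called lower in any Cre+ group. In naive microglia Dicer1 stood at 18.55, 11.1 and 12.07 CPM in Cre- and at 21.81, 22.06 and 24.31 CPM in Cre+ libraries. This was a rise of 0.72 ± 0.16 on the log2 scale (SE, n = 3 per group, edgeR, adjusted p = 0.00151). With correction for GC content and transcript length the rise was 0.38 (adjusted p = 0.0448). In demyelination Cre- libraries held 23.07, 22.7 and 15.18 CPM and Cre+ libraries 11.62, 15.71 and 17.49 CPM (log2 -0.45 ± 0.16, adjusted p = 0.0922). Tamoxifen at the start left 33.86 to 39.11 CPM in Cre- and 32.41 to 35.21 CPM in Cre+ (log2 -0.10 ± 0.16, adjusted p = 0.909). At the peak the values were 30.62 to 34.08 CPM in Cre- and 30.45 to 32.44 CPM in Cre+ (log2 -0.06 ± 0.16, adjusted p = 0.85). The genotype effect on Dicer1 differed between demyelination and naive by -1.17 ± 0.23 (adjusted p = 0.00165). Gene totals sum all exons, so loss of the deleted segment was not resolved here. Genotype effects are therefore those of Cre+ against Cre-, which differ in creERT2 at Cx3cr1 as well as in the intended Dicer1 deletion.

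Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the fractalkine receptor gene that carries creERT2 in Cre+ mice, is the second genotype marker. Of the 12 Cre+ libraries, 9 held 41.46% to 59.27% of the mean of the Cre- libraries of their state. The other 3 held far less. Naive Cre+ replicate 1 had 227.1 CPM (2.18%), and demyelination Cre+ replicates 1 and 3 had 104.3 CPM (1.87%) and 89.62 CPM (1.61%). The difference in Cx3cr1 between genotypes did not pass the threshold in any state. It was -1.76 ± 0.97 (adjusted p = 0.197) in naive and -2.74 ± 1.01 (adjusted p = 0.105) in demyelination, where the Cre+ libraries spread most. In remyelination it was -0.94 ± 0.95 (adjusted p = 0.832) at the start and -1.08 ± 0.95 (adjusted p = 0.526) at the peak. Each gene has a single dispersion across all 24 libraries, so the 3 low libraries widened these errors in every state. Without them, a fit added after seeing the data, Cx3cr1 was lower by 1.24 (adjusted p = 4.83e-07) in naive and by 1.23 (adjusted p = 0.000677) in demyelination, where a lone Cre+ library was left.

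**Figure D1:**
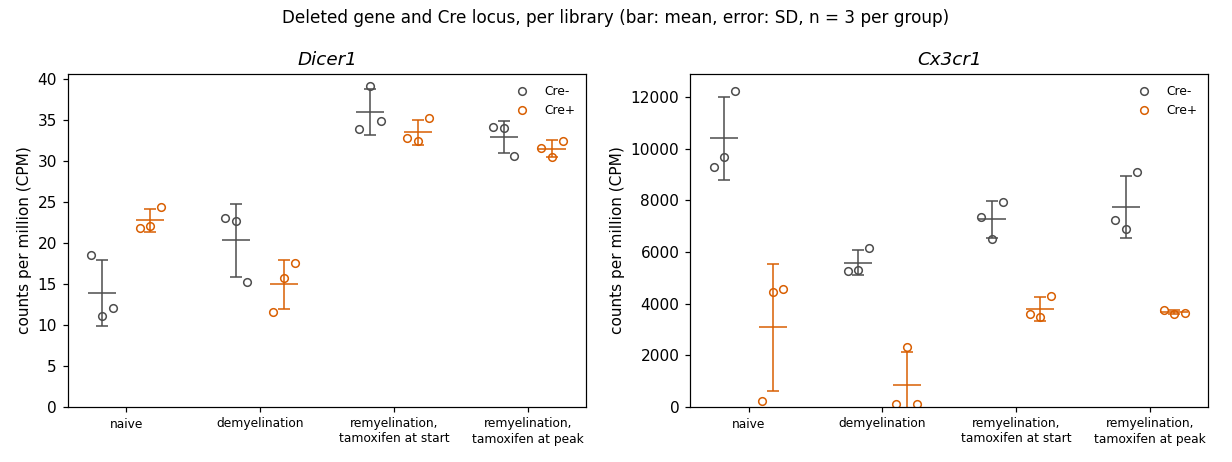
CPM of Dicer1 and Cx3cr1 in every library, by state and genotype (circles are libraries, bars means, error bars SD, n = 3 per group).

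The first comparison asked what differs between Cre+ and Cre- in resting microglia. In the naive state 4982 of 17579 genes differed between genotypes, 2580 higher and 2402 lower in Cre+. Among eligible genes (mean log2 CPM of at least 2, no overlap between groups) the transcription factor Cebpb (chromosome 2, 167688915 to 167690418), a regulator of myeloid inflammatory genes, rose most. It went from 1.801 ± 1.96 to 26.59 ± 16.2 CPM (SD, n = 3), a log2 change of 4.14 ± 1.05 (SE, adjusted p = 0.00706), and ranged from 8.377 to 39.31 CPM within Cre+. The chemokine receptor Ccr1 (chromosome 9, 123962124 to 123968692), which guides myeloid cells along CCL3 gradients, fell most of the eligible genes. It went from 33.96 ± 3.23 to 2.806 ± 1.72 CPM (log2 -3.52 ± 0.39, adjusted p = 5.93e-06).

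Alb, the albumin gene, rose from 1.665 ± 0.305 to 18.11 ± 1.6 CPM (log2 3.45 ± 0.34, adjusted p = 2.18e-07) and the deubiquitinase gene Otud1 from 15.59 ± 11 to 107.9 ± 24.6 CPM (2.83 ± 0.44, adjusted p = 0.000179). Coro2a, which encodes an actin-binding coronin, rose from 17.16 ± 2.02 to 115.5 ± 22.6 CPM (2.75 ± 0.27, adjusted p = 1.69e-06). The sialic acid receptor Cd22, which restrains microglial phagocytosis, fell by 2.63 ± 0.34 (adjusted p = 2.89e-05). Cd79b, a B-cell receptor component also expressed by microglia, fell from 63.24 ± 3.45 to 13.87 ± 5.39 CPM (-2.17 ± 0.37, adjusted p = 0.000374). The lipid droplet gene Plin3 (-2.16 ± 0.17, adjusted p = 1.04e-08) and the acetylcholine receptor clustering gene Rapsn (-2.26 ± 0.2, adjusted p = 5.07e-08) fell as well.

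For gene lists, counts adjusted over all genes come first, and counts adjusted over the list alone are marked "alone". In naive Cre+ microglia 15 of 25 disease-associated genes, which microglia induce around damage, fell and 1 rose (17 and 1 adjusted over the list alone). Their median log2 change was -0.61 (camera adjusted p = 2.19e-10, adjusted p = 0.247 with an estimated correlation). Apoe, which carries lipids out of cells (-1.95), the tetraspanin gene Cd63 (-1.49) and the cathepsin gene Ctsb (-0.88) were among them. Of 30 interferon response genes 13 fell and 1 rose (alone 17 and 2), with a median of -0.39 (adjusted p = 9e-04, adjusted p = 0.669 with an estimated correlation). The antiviral genes Ifit1 (-1.29) and Mx1 (-1.21) fell. MHC class II genes, which present antigen, fell in 5 of 10 cases and rose in 0 (alone 6 and 0), with a median of -0.59 (adjusted p = 0.0138) and H2-DMa at -0.85. Of 17 cytokine and chemokine genes 8 fell, among them Ccl3 (-1.68) and Ccl4 (-1.64), and 1, the inflammasome sensor Nlrp3, rose (0.70). These counts were the same alone, and the median was -0.52 (adjusted p = 0.0024). Cholesterol biosynthesis genes fell in 7 of 23 cases both ways (median -0.40, adjusted p = 0.00693), Stard4 by -1.37. The class II, cytokine and cholesterol lists each had adjusted p = 0.669 with an estimated correlation. Lysosome genes fell in 12 and rose in 5 of 33 cases (alone 15 and 5), with a median of -0.14 (adjusted p = 0.02) and Ctsd at -0.71. Astrocyte markers fell in 3 of 11 cases (alone 4), with a median of -0.73 (adjusted p = 0.0138) and Slc1a3 at -0.56. Both had adjusted p = 0.704 with an estimated correlation. The lysosome list was not called without Cre- replicate 3 or Cre+ replicate 2 (adjusted p up to 0.085), and its median was -0.22 without Cre+ replicate 1. Astrocyte markers were not called without Cre- replicate 2 (adjusted p = 0.0912), nor the class II list with GC content and length corrected (0.109).

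Cell cycle genes rose in 19 of 27 cases and fell in 0 (alone 20 and 0). Their median was 1.54 (camera adjusted p = 2.76e-06, adjusted p = 0.669 with an estimated correlation). The S-phase regulator E2f1 rose by 1.93, and the mitotic kinase genes Aurka and Plk1 by 1.62 and 1.54. Mki67 held 3.463 CPM in Cre+ replicate 1, inside the Cre- values of 2.799 to 4.652, against 18.2 and 18.35 CPM in Cre+ replicates 2 and 3. Genes of the miRNA machinery other than Dicer1 rose in 7 of 12 cases and fell in 0 (alone 9 and 0). Their median was 0.46 (adjusted p = 9.29e-06), and this call held (adjusted p = 0.018 with an estimated correlation). Ago2, which binds mature miRNAs, rose by 1.11, and its partners Tnrc6c and Tnrc6a by 1.10 and 0.74. With correction for GC content and length these rises were 0.69, 0.64 and 0.46, all called, and the list had adjusted p = 0.00905. Let-7 targets rose in 10 and fell in 1 of 20 cases (alone 11 and 1), Map4k3 by 1.34. The median was 0.46 (adjusted p = 0.0024, adjusted p = 0.14 with an estimated correlation). TGF-beta signalling genes rose in 7 of 16 cases and fell in 0 (alone 7 and 1), Smad6 by 1.46. Their median was 0.27 (adjusted p = 0.0138, adjusted p = 0.399 with an estimated correlation), and the list was not called after correction for GC content and length (adjusted p = 0.212).

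Homeostatic genes did not shift together in naive microglia. Of 20, 4 rose and 2 fell both ways (median 0.09, camera adjusted p = 0.749). Sparc (0.76) and Tgfbr1 (0.82) rose and Fcrls (-1.26) fell. Phagocytosis receptors (8 higher and 6 lower of 24, alone 9 and 7), lipid efflux and storage genes (5 and 4 of 18, alone 5 and 5), p53 targets (3 and 3 of 21 both ways) and miR-155 and miR-146a targets (4 and 0 of 12, alone 5 and 0) were not called either. Dissociation genes were 3 higher and 4 lower of 16 both ways, with a median of -0.24 against a mean of 0.15. The heat shock gene Hspa1b among them rose (2.73, uncertain because Hspa1a is a near-identical copy). Growth factors (2 and 3 of 13, alone 3 and 4) also had a median (0.16) and a mean (-0.11) of opposite sign. The other lists were not called (adjusted p of at least 0.149).

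Longer genes tended to be higher in naive Cre+ microglia (Spearman rho 0.35 across 10789 genes, which are not independent), and 3681 of the 4982 genes were called with correction for GC content and length as well. With replicate number as a block the adjusted p of Cebpb was 0.0786. It was the only one of the 35 called genes named for this comparison to lose its call that way, and none did when a library was left out.

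**Figure D2:**
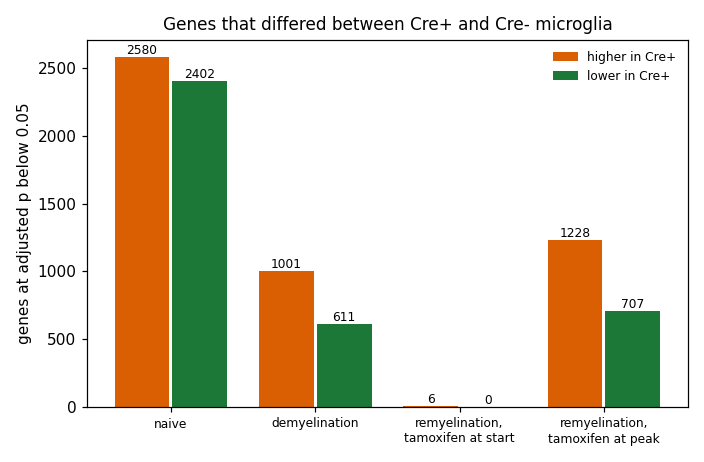
Number of genes called higher or lower in Cre+ than in Cre- microglia in each state (edgeR, adjusted p below 0.05, 17579 genes tested).

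The second comparison asked how Cre+ and Cre- microglia differ in cuprizone demyelination. Here 1612 genes differed, 1001 higher and 611 lower in Cre+. The class II chain gene H2-Aa (chromosome 17, 34282744 to 34287823), which presents peptides to CD4 T cells, fell from 496.4 ± 14.8 to 140.1 ± 18.7 CPM (SD, n = 3). This was a log2 change of -1.82 ± 0.28 (SE, adjusted p = 0.00104). H2-Ab1 fell from 811.4 ± 50.2 to 278.3 ± 29.4 CPM (-1.54 ± 0.25, adjusted p = 0.00145) and H2-Eb1 from 275.6 ± 24.1 to 74.42 ± 13.2 CPM (-1.89 ± 0.3, adjusted p = 0.00132). Mki67, a marker of cycling cells, stood at 26.89 to 28.91 CPM in Cre+ and at 6.423 to 7.946 CPM in Cre- libraries.

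The largest rise among eligible genes was that of Lgi2 (chromosome 5, 52533517 to 52566462), a secreted protein gene linked to epilepsy. It went from 2.651 ± 1.61 to 37.05 ± 29 CPM (log2 3.82 ± 0.74, adjusted p = 0.00576, and 0.0692 with replicate number as a block). The B-cell chemokine Cxcl13 rose from 3.5 ± 1.27 to 39.11 ± 33.6 CPM (3.49 ± 0.61, adjusted p = 0.00219), the p53 effector Perp by 2.69 ± 0.4 (adjusted p = 0.000816) and the uroplakin gene Upk1b by 2.49 ± 0.38 (adjusted p = 0.00114). Lgi2 held 36.85 and 66.19 CPM in Cre+ replicates 1 and 3, the low-Cx3cr1 libraries, and 8.113 CPM in Cre+ replicate 2. The matrix protein gene Postn fell most of them, from 251 ± 27 to 56.66 ± 37.7 CPM (-2.15 ± 0.31, adjusted p = 0.000692). The monocyte chemokine receptor Ccr2 fell from 48.16 ± 14.6 to 16.22 ± 7.24 CPM (-1.56 ± 0.27, adjusted p = 0.00196).

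Cell cycle genes in demyelination rose in 22 of 27 cases and fell in 0 (26 and 0 adjusted over the list alone), with Birc5 at 1.70, Aurka at 1.55 and Cdk1 at 1.23. Their median was 1.47 (camera adjusted p = 1.04e-23, adjusted p = 0.335 with an estimated correlation). Interferon genes rose in 8 of 30 cases and fell in 0 (alone 9 and 0), with Ifi44 at 1.92 and Rsad2 at 0.94. Their median was 0.25 (adjusted p = 4.49e-05, adjusted p = 0.523 with an estimated correlation). Lysosome genes rose in 9 and fell in 1 of 33 cases (alone 12 and 3), with the hydrolase genes Gusb at 0.77, Ctsz at 0.48 and Ctsd at 0.45. Their median was 0.15 (adjusted p = 0.00145, adjusted p = 0.543 with an estimated correlation). P53 targets rose in 4 of 21 cases (alone 9, and 2 lower), Phlda3 by 1.51, with a median of 0.16 (adjusted p = 0.00418, adjusted p = 0.492 with an estimated correlation). Phagocytosis receptors rose in 4 of 24 cases (alone 7), Itgam by 0.47, with a median of 0.15 (adjusted p = 0.0236, adjusted p = 0.523 with an estimated correlation). Cholesterol biosynthesis genes rose in 2 of 23 cases both ways, Hmgcs1 by 0.44, with a median of 0.17 (adjusted p = 0.0256, adjusted p = 0.808 with an estimated correlation).

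Without demyelination Cre- replicate 3 interferon genes (median 0.11, adjusted p = 0.0567) and phagocytosis receptors (adjusted p = 0.0574) were not called, and the lysosome median was 0.09. Without Cre- replicate 2 the interferon median was 0.42. Cholesterol biosynthesis was not called without Cre- replicate 1 or Cre+ replicate 2 (median 0.11) or 3 (up to 0.242). Without the 3 low-Cx3cr1 libraries p53 targets (adjusted p = 0.185) and phagocytosis receptors (adjusted p = 0.103) were not called.

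MHC class II genes split into 5 lower and 2 higher of 10 both ways, with the invariant chain Cd74 at -1.30 and a median of -0.65 (camera adjusted p = 0.00506, adjusted p = 0.523 with an estimated correlation). Monocyte markers fell in 3 of 9 cases (alone 5), Itga4 by -1.29, with a median of -1.22 (adjusted p = 0.00145, adjusted p = 0.492 with an estimated correlation). Border-associated macrophage markers fell in 2 of 10 cases (alone 4), F13a1 by -1.08, with a median of -0.44 (adjusted p = 0.00441, adjusted p = 0.523 with an estimated correlation). T, NK and B cell markers fell in 3 of 8 cases (alone 4), with a median of -0.67 (adjusted p = 0.00692, adjusted p = 0.414 with an estimated correlation). Without Cre- replicate 3 or Cre+ replicate 1 the call of F13a1 ended (up to 0.0747). The class II list was not called without Cre+ replicate 2 (adjusted p = 0.216), and the median of T, NK and B cell markers was -0.28 without Cre- replicate 2.

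Disease-associated genes were not called as a list in demyelination. Of 25, 5 were higher and 1 lower (alone 6 and 2), with a median of 0.12 (camera adjusted p = 0.132), and the cystatin gene Cst7 rose by 1.28. Cytokines were 3 higher and 1 lower of 17 (alone 3 and 2), with a median of 0.07 (adjusted p = 0.124), and the monocyte attractants Ccl2 and Ccl12 rose by 1.64 and 1.17. Of 20 homeostatic genes 2 rose, Sparc by 0.91, and 0 fell (adjusted p = 0.173). The miRNA machinery had a median of 0.05 (adjusted p = 0.729) and neutrophil markers one of 1.13 (adjusted p = 0.23), each with 0 genes past the edgeR threshold.

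The counts in demyelination depended on the libraries. Leaving out Cre+ replicate 1 gave 417 genes, and leaving out Cre- replicate 2, Cre- replicate 3 or Cre+ replicate 3 gave 826, 810 and 803. Without Cre- replicate 1 there were 941, and without Cre+ replicate 2 there were 2114. Calls ended without Cre+ replicate 1 for Rsad2 (adjusted p = 0.0584) and Ctsz (0.0696) and without Cre+ replicate 3 for Hmgcs1 (0.0706). Phlda3 lost its call without Cre- replicate 2 or 3 or Cre+ replicate 1 or 3 (up to 0.0859). Without the 3 low-Cx3cr1 libraries, which leaves a lone Cre+ library, assumed to vary like the other groups, 81 genes were called (75 higher, 6 lower). Of these, 78 were among the 1612. Here 22 of the 28 called genes named for it lost their call and 11 shrank by over 1.5 times. Cxcl13 stood at 0.97, Lgi2 at 1.66, Upk1b at 1.15, Ifi44 at 0.53 and Rsad2 at 0.35. H2-Aa lost its call at a similar size (log2 -1.75, adjusted p = 0.216), while 16 cell cycle genes were called.

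The third comparison asked how the genotypes differ after cuprizone and recovery on normal diet, with tamoxifen at the start. In this state 6 genes differed by edgeR, all higher in Cre+ (1657 genes at an unadjusted p below 0.05). Other fits also called lower genes: DESeq2 11 higher and 65 lower, limma-voom 11 and 15, no filter 37 and 44, only the groups compared 23 and 17. Hsph1 (chromosome 5, 149614287 to 149636376), a co-chaperone of HSP70, rose from 22.75 ± 1.74 to 54.43 ± 1.2 CPM (SD, n = 3), a log2 change of 1.26 ± 0.15 (SE, adjusted p = 0.000139). Dnajb1 rose from 77.96 ± 8.49 to 137.4 ± 11.7 CPM (0.82 ± 0.12, adjusted p = 0.00328) and Hspe1 from 38.1 ± 4.39 to 65.67 ± 2.76 CPM (0.79 ± 0.12, adjusted p = 0.00328). The chaperone gene Hsp90aa1 rose by 0.76 ± 0.14 (adjusted p = 0.0343) and the stress-response gene Gadd45g by 0.75 ± 0.13 (adjusted p = 0.0167). Of the 6 genes, 5 were also higher in naive, 3 in demyelination and 4 at the peak, Hsp90aa1 in all 3 (1.58, 0.72 and 0.56, looked up after seeing this result). At the peak its call ended without Cre- replicate 2 or Cre+ replicate 1 (adjusted p up to 0.0672). Without Cre- replicate 3 a single gene was called and without Cre+ replicate 1 there were 2. Dnajb1 lost its call in both of these fits and Hspe1 in the first (adjusted p up to 0.0862). Hsp90aa1 lost it without any library but Cre- replicate 2 (up to 0.208), and Gadd45g without Cre- replicate 1 or 3 or Cre+ replicate 1 or 3 (up to 0.114).

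No member of the 30 lists passed the edgeR threshold at the start, but camera called 12 lists. Disease-associated genes had a median of -0.30 (11 lower of 25 adjusted over the list alone, camera adjusted p = 3.02e-09). Cd63 stood at -0.57 (adjusted p = 0.123) and Clec7a at -0.61 (0.273). Dissociation and immediate early genes had a median of -0.70 (alone 2 higher and 10 lower of 16, adjusted p = 2.28e-06), with Egr1 at -0.96 (0.125). Cytokines had one of -0.56 (alone 3 lower of 17, adjusted p = 2.22e-05), with Ccl3 at -1.29 (0.171) and Il1b at -1.23 (0.219). Lysosome genes stood at -0.15 (alone 2 lower of 33, adjusted p = 1.36e-07), interferon genes at -0.15 (alone 0 of 30, adjusted p = 0.0134) and cell cycle genes at -0.35 (alone 1 lower of 27, adjusted p = 0.000953), with Mki67 at -1.08 (0.491). Markers of neutrophils (-1.62, adjusted p = 0.00375), monocytes (-0.99, adjusted p = 0.0459) and T, NK and B cells (-0.26, alone 2 lower of 8, adjusted p = 0.0459) were lower as groups. Retnlg, a neutrophil gene, stood at -2.57 (0.412). MHC class II genes (0.12, adjusted p = 0.0459), endothelial markers (0.56, adjusted p = 0.00341) and mural markers (1.07, alone 4 higher of 5, adjusted p = 9.29e-06) were higher as groups, with Vtn at 1.16 (0.29). None of the 12 was called by fry or with an estimated correlation, where adjusted p ranged from 0.385 to 0.827.

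Many of these calls rested on single libraries. Without Cre- replicate 2, whose mean log2 deviation over the neutrophil list was 2.65, the medians were -0.76 for neutrophil, -0.37 for monocyte, -0.17 for cytokine and -0.34 for dissociation genes, and Retnlg stood at -1.52, Il1b at -0.75 and Clec7a at -0.37. Calls of neutrophil markers ended without it or Cre+ replicate 3 (adjusted p up to 0.198), and of monocyte markers without it, Cre- replicate 3 or Cre+ replicate 3 (up to 0.608). T, NK and B cell markers lost theirs without Cre- replicate 1 or 3 or Cre+ replicate 2 or 3 (up to 0.278, median -0.53 without Cre+ replicate 1). Interferon genes lost it without Cre- replicate 3 or Cre+ replicate 2 or 3 (up to 0.282, median -0.10 without Cre+ replicate 2, -0.29 without Cre+ replicate 1). Class II genes lost it without Cre- replicate 1 or 2 or Cre+ replicate 1 (up to 0.72, median -0.06 without the last and 0.25 without Cre- replicate 3). Cell cycle genes lost it without Cre+ replicate 3 (median -0.09, adjusted p = 0.143). Endothelial markers lost it without Cre- replicate 3 or Cre+ replicate 3 (up to 0.147, median 0.27 without the latter and 0.94 without Cre- replicate 2). DESeq2 called Cd63 (adjusted p = 0.00261), Egr1 (0.000459), Ccl3 (0.00598) and Il1b (0.0201).

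The fourth comparison asked how the genotypes differ with tamoxifen at the peak (week 5 of cuprizone). Here 1935 genes differed, 1228 higher and 707 lower in Cre+. Proliferation genes were many times higher in Cre+. Mki67 (chromosome 7, 135689784 to 135716361) rose from 2.431 ± 0.55 to 50.4 ± 0.986 CPM (SD, n = 3), a log2 change of 4.37 ± 0.45 (SE, adjusted p = 1.02e-05). The topoisomerase gene Top2a rose from 4.013 ± 0.955 to 53.85 ± 12.6 CPM (3.76 ± 0.51, adjusted p = 0.000142) and the nucleotide-supply gene Rrm2 from 1.179 ± 0.556 to 22.68 ± 7.81 CPM (4.29 ± 0.65, adjusted p = 0.000347). The mitotic genes Pbk (4.33 ± 0.46, adjusted p = 8.7e-06) and Ccnb1 (3.66 ± 0.4, adjusted p = 9.98e-06) rose too. Of the eligible genes Cd22 fell most, from 35.86 ± 7.69 to 8.023 ± 2.06 CPM (-2.16 ± 0.33, adjusted p = 0.000352). The checkpoint receptor Lag3 fell from 86.91 ± 12.7 to 30.47 ± 10.2 CPM (-1.51 ± 0.2, adjusted p = 4.67e-05), as did Rapsn (-1.51 ± 0.22, adjusted p = 5.6e-05). The pericyte receptor Pdgfrb fell by 1.48 ± 0.32 (adjusted p = 0.00323, and 0.0634 without Cre- replicate 2). Without Cre- replicate 2, Cre+ replicate 3 or Cre+ replicate 2 the count was 883, 1044 and 1270.

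At the peak 26 of 27 cell cycle genes rose and 0 fell (27 and 0 adjusted over the list alone), Aurkb by 3.43 and Cdk1 by 2.76. Their median was 3.10 (camera adjusted p = 2.54e-65), and this call held (adjusted p = 0.00684 with an estimated correlation). P53 targets rose in 8 of 21 cases and fell in 0 both ways, among them the cell-cycle inhibitor Cdkn1a (2.35), Perp (2.01) and Ccng1 (0.58), with a median of 0.27 (adjusted p = 6.02e-06) that was 0.43 without Cre- replicate 1. The miRNA machinery rose in 4 of 12 cases both ways, Tnrc6b by 0.51 and Ago2 by 0.45, with a median of 0.24 (adjusted p = 0.00649). Let-7 targets rose in 3 of 20 cases (alone 8), Cdc25a by 1.03, with a median of 0.31 (adjusted p = 0.00318). Each of these 3 lists had adjusted p = 0.118 with an estimated correlation. Disease-associated genes fell in 7 of 25 cases and rose in 0 (alone 10 and 1), Cd63 by -1.08, Clec7a and Apoe by -0.91 and Ctsb by -0.64. Their median was -0.40 (adjusted p = 1.23e-07, adjusted p = 0.315 with an estimated correlation). Lysosome genes fell in 7 and rose in 2 of 33 cases (alone 11 and 3), with Ctsd at -0.67 and Ctss at -0.53. Their median was -0.13 (adjusted p = 0.00137, adjusted p = 0.542 with an estimated correlation). Without Cre- replicate 3 it was -0.08 and the list was not called (adjusted p = 0.0785). Apoe was not called without Cre- replicate 2 (adjusted p = 0.0517), nor Ago2 without Cre- replicate 1 or 2 or Cre+ replicate 2 or 3 (up to 0.142). With the replicate block the adjusted p of Ago2 was 0.0527.

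Markers of other cells moved apart at the peak. Neutrophil markers rose in 2 of 12 cases (alone 11), with a median of 3.11 (camera adjusted p = 0.00706, adjusted p = 0.707 with an estimated correlation). It was not called without Cre+ replicate 3 (median 0.84, adjusted p = 0.334). The genes called were the granule genes Camp (3.44, adjusted p = 0.0459) and Elane (4.88, adjusted p = 0.0499). Both lost their call without Cre+ replicate 3 or any 1 of the Cre- libraries (up to 0.567 and 0.548, with log2 values of 1.01 and 1.78 without Cre+ replicate 3), and with the replicate block (0.205 and 0.194). Camp stood at 39.24, 33.8 and 518.2 CPM in Cre+ and at 13.9 to 22.06 CPM in Cre-. Mural markers fell in 4 of 5 cases both ways, with a median of -1.48 (adjusted p = 0.00116, adjusted p = 0.315 with an estimated correlation). Vtn (-1.47) and Rgs5 (-1.92) lost their calls without Cre- replicate 1 or 2 or Cre+ replicate 1 or 3 (up to 0.12 and 0.125). Astrocyte markers fell in 2 of 11 cases (alone 10), with a median of -0.91 (adjusted p = 2.21e-06, adjusted p = 0.359 with an estimated correlation). They were the glutamate transporter gene Slc1a3 (-0.76) and Gfap (-1.12, adjusted p up to 0.113 without Cre- replicate 2 or Cre+ replicate 1). Endothelial markers fell in 1 of 7 cases both ways, with a median of -0.84 (adjusted p = 0.0086, adjusted p = 0.52 with an estimated correlation), -0.49 without Cre- replicate 2 and -1.66 without Cre+ replicate 2. Cytokines were not called, with 3 higher and 1 lower of 17 (alone 4 and 3), Ccl2 at 1.69 and a median of -0.14 against an upward camera direction (adjusted p = 0.941). Homeostatic genes were not called either, with 3 higher and 1 lower of 20 (alone 5 and 2), Sparc at 0.72 and Tgfbr1 at 0.73.

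**Figure D3:**
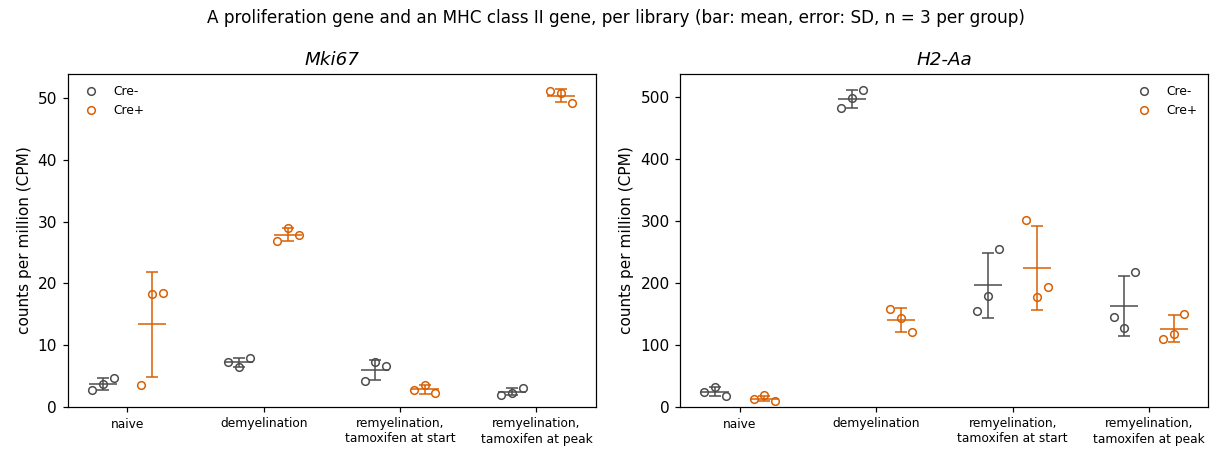
CPM of Mki67 and H2-Aa in every library, by state and genotype (circles are libraries, bars means, error bars SD, n = 3 per group). With tamoxifen at the peak Mki67 lies at 49.27 to 51.1 CPM in Cre+ and 1.988 to 3.046 CPM in Cre-.

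Genotype effects were compared between states across the 17579 genes, which are not independent. Naive and peak effects were most alike (Pearson r 0.41, Spearman rho 0.44). In both, 729 genes were higher and 452 lower, where independent calls would give 180.2 and 96.6, and 12 were called in opposite directions. Demyelination and peak (r 0.32, rho 0.29) shared 427 higher and 142 lower genes against 69.93 and 24.57 for independent calls, with 10 opposite. Naive and demyelination (r 0.19, rho 0.16) shared 398 higher and 223 lower genes against 146.9 and 83.49, with 137 opposite. The start state had r of 0.07, 0.03 and -0.10 and rho of 0.15, -0.03 and -0.02 with naive, demyelination and peak. Among the 7822 genes with a mean log2 CPM of at least 4 these were r 0.28, -0.07 and 0.07 and rho 0.31, -0.15 and 0.16, and r with naive was 0.16 with GC content and length corrected as well. There naive and demyelination had r 0.13 and rho 0.06 and shared 207 higher and 127 lower genes against 142 and 62.55, with 117 opposite. The other pairs had r 0.55 (naive and peak) and 0.46 (demyelination and peak). Of 401 genes called in the same direction in the 3 other states, 204 (50.9%) had that sign at the start.

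**Figure D4:**
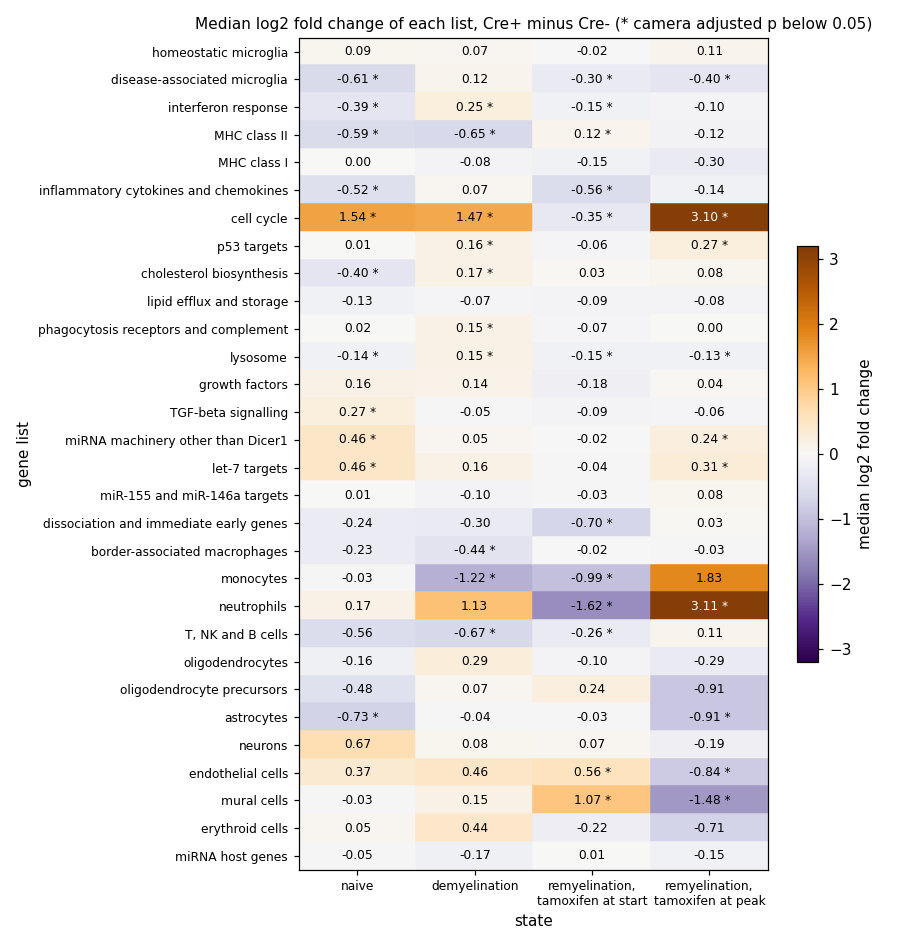
Median log2 fold change (Cre+ minus Cre-) of the genes of each list in each state, coloured from purple (lower in Cre+) to orange (higher), with an asterisk where camera gave an adjusted p below 0.05 at its preset correlation.

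The interaction of genotype with demyelination asked which genotype effects differ between demyelination and the naive state. It held 2769 genes, 1401 with a more positive and 1368 with a more negative effect in demyelination. Longer genes tended to be more negative (rho -0.38), and 1728 of the 2769 were called with GC content and length corrected as well. The effect on Cst7, a cysteine protease inhibitor induced in activated microglia, was more positive by 3.09 ± 0.33 (adjusted p = 1.13e-05) and that on Ccr1 by 2.5 ± 0.51 (adjusted p = 0.00368). The keratin gene Krt2 had the highest value among eligible genes (4.33 ± 1.02, adjusted p = 0.0123, and 0.0783 with replicate number as a block). Effects on Postn (-3.25 ± 0.44, adjusted p = 0.000242) and Cebpb (-5.23 ± 1.34, adjusted p = 0.0146) were more negative, the latter with adjusted p = 0.0513 without naive Cre- replicate 2 and 0.119 with the block.

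Disease-associated genes were more positive in demyelination than in naive in 12 of 25 cases and more negative in 0 (15 and 0 adjusted over the list alone), Cd63 by 1.53 and Ctsb by 1.02. Their median was 0.81 (camera adjusted p = 5.54e-13, adjusted p = 0.189 with an estimated correlation). Interferon genes were more positive in 13 of 30 cases (alone 15), Ifit1 by 1.95 and Rsad2 by 1.93, with a median of 0.71 (adjusted p = 1.63e-09). Cytokines were more positive in 9 and more negative in 1 of 17 cases (alone 10 and 1), Ccl12 by 1.42, with a median of 1.19 (adjusted p = 3.3e-05). Cholesterol biosynthesis genes were more positive in 7 of 23 cases (alone 10), Stard4 by 2.09, with a median of 0.51 (adjusted p = 3.89e-05). Lysosome genes were 14 more positive and 1 more negative of 33 (alone 19 and 3), with a median of 0.35 (adjusted p = 1.8e-05). These last 4 lists had adjusted p = 0.31 with an estimated correlation. Without the low-Cx3cr1 libraries Rsad2 stood at 1.21 and Ccl12 at 0.87, both called. The miRNA machinery was more negative in 5 of 12 cases (alone 7), Ago2 by -1.15 and Tnrc6c by -1.12, with a median of -0.38 (adjusted p = 0.000125, adjusted p = 0.0612 with an estimated correlation). With GC content and length corrected Ago2 differed by -0.69 and Tnrc6c by -0.63, both called. Let-7 targets were 3 more negative and 1 more positive of 20 (alone 4 and 1), Map4k3 at -1.88, with a median of -0.36 (adjusted p = 0.0141, adjusted p = 0.246 with an estimated correlation). TGF-beta signalling genes were more negative in 3 of 16 cases both ways, Smad6 by -1.73, with a median of -0.23 (adjusted p = 0.0446, adjusted p = 0.31 with an estimated correlation). These last 3 lists were not called with GC content and length corrected (adjusted p = 0.0501, 0.0501 and 0.363). TGF-beta also lost its call without demyelination Cre- replicate 1 or Cre+ replicate 2 or naive Cre- replicate 2 or Cre+ replicate 1 or 3 (up to 0.0992). Cell cycle genes did not differ as a group (2 and 1 of 27, median 0.14, adjusted p = 0.29).

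The interaction between demyelination and remyelination with tamoxifen at the start held 657 genes, 140 with a more positive and 517 with a more negative effect at the start. Effects on H2-Eb1 (2.26 ± 0.42, adjusted p = 0.0115) and H2-Aa (2.02 ± 0.39, adjusted p = 0.0129) were more positive. Those on the ubiquitin-conjugating mitotic gene Ube2c (-3.39 ± 0.61, adjusted p = 0.00776) and Mki67 (-3.03 ± 0.6, adjusted p = 0.0138) were more negative. Without start Cre- replicate 2 the adjusted p of H2-Aa was 0.05 and that of Mki67 0.053. Cell cycle genes were more negative in 13 of 27 cases (24 adjusted over the list alone), with a median of -1.84 (camera adjusted p = 3.06e-22). Lysosome genes were more negative in 8 of 33 cases (alone 20), Glb1 by -0.90, with a median of -0.34 (adjusted p = 7.74e-09). Both lists had adjusted p = 0.399 with an estimated correlation. Disease-associated genes were more negative in 5 of 25 cases (alone 13), Cst7 by -1.92, with a median of -0.44 (adjusted p = 2.45e-06). Interferon genes were so in 3 of 30 cases (alone 10), with a median of -0.40 (adjusted p = 1.04e-06), and cytokines in 3 of 17 (alone 8), Ccl2 by -1.81, with a median of -0.85 (adjusted p = 0.000121). Phagocytosis receptors followed in 4 of 24 cases (alone 6), Gas6 by -0.83 (0.0704 without demyelination Cre+ replicate 1), with a median of -0.24 (adjusted p = 0.00555). MHC class II genes were 5 more positive and 1 more negative of 10 both ways, with a median of 0.73 (adjusted p = 0.00023). These 5 lists had adjusted p = 0.415 with an estimated correlation. With 0 genes called, border-associated macrophage markers had a median of 0.46 (adjusted p = 0.0146, adjusted p = 0.642 with an estimated correlation) and neutrophil markers one of -2.74 (adjusted p = 0.0061, adjusted p = 0.665 with an estimated correlation).

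This interaction count was 97, 1158 and 384 without demyelination Cre+ replicates 1, 2 and 3, and 375, 310 and 168 without demyelination Cre- replicates 1, 2 and 3. It was 380 and 113 without start Cre- replicates 1 and 2, and 355 and 119 without start Cre+ replicates 1 and 2. Other fits gave more: DESeq2 1439, limma-voom 1549, no filter 1026 and only the groups compared 1062. Without the low-Cx3cr1 libraries, and so with a lone demyelination Cre+ library, 43 genes were called. Then 6 of the 8 called genes named for it lost their call, but only Gas6 shrank by over 1.5 times (-0.55), and H2-Aa stayed at 1.98 (adjusted p = 0.225). Nor were phagocytosis receptors (adjusted p = 0.0515) and border-associated macrophage markers (0.0619) called there. The latter also lost their call without demyelination Cre- replicate 3 or start Cre+ replicate 1 (up to 0.27, median 0.17 without the latter). Neutrophil markers lost it without demyelination Cre- replicate 1, start Cre- replicate 2 or start Cre+ replicate 3 (up to 0.0592, median -1.77 without start Cre- replicate 2). The interferon median was -0.25 without demyelination Cre- replicate 3 and the cytokine median -0.50 without start Cre- replicate 2.

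The interaction of genotype with tamoxifen timing held 662 genes, 505 with a more positive and 157 with a more negative effect at the peak than at the start. The effect on Mki67 was more positive by 5.45 ± 0.65 (adjusted p = 0.000234) and that on Top2a by 4.57 ± 0.74 (adjusted p = 0.0023). Effects on the pericyte genes Vtn (-2.64 ± 0.52, adjusted p = 0.00772) and Pdgfrb (-2.41 ± 0.44, adjusted p = 0.00208) were more negative. So was that on Cd22 (-2.14 ± 0.44, adjusted p = 0.0114, and 0.0766 with the replicate block). The neutrophil gene Retnlg had the highest value among eligible genes (6.18 ± 1.63, adjusted p = 0.0445, and 0.159 with the replicate block). Leaving out start Cre- replicate 1, peak Cre- replicate 1 or peak Cre+ replicate 1 or 2 kept this call, and leaving out any other library of these groups ended it (up to 0.463, with a difference of 2.45 without peak Cre+ replicate 3). Cell cycle genes were more positive in 24 of 27 cases (26 adjusted over the list alone), Aurkb by 3.98. Their median was 3.39 (camera adjusted p = 9.06e-63), and this call held (adjusted p = 0.008 with an estimated correlation). P53 targets were more positive in 2 of 21 cases (alone 5), Cdkn1a by 2.22, with a median of 0.40 (adjusted p = 0.000505). The miRNA machinery had 0 of 12 genes called (alone 4 more positive) and a median of 0.28 (adjusted p = 0.019), and let-7 targets were more positive in 2 of 20 cases both ways, with a median of 0.40 (adjusted p = 0.0119). These 3 lists had adjusted p = 0.202 with an estimated correlation. Cytokines were more positive in 1 of 17 cases (alone 5, and 1 more negative), Ccl2 by 1.86, with a median of 0.51 (adjusted p = 0.0261), and dissociation genes in 1 of 16 (alone 3), with a median of 0.46 (adjusted p = 0.00987). Both had adjusted p = 0.702 with an estimated correlation. Without start Cre- replicate 2 neither was called (medians 0.16 and 0.15) and the p53 median was 0.21. Cytokines also lost their call without start Cre+ replicate 2, peak Cre- replicate 3 or peak Cre+ replicate 1 (adjusted p up to 0.322). So did dissociation genes without peak Cre+ replicate 1 (up to 0.191) and the miRNA machinery without peak Cre+ replicate 2 (0.0579).

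Markers of other cells also differed between timings. Neutrophil markers were more positive in 1 of 12 cases (11 adjusted over the list alone), with a median of 4.78 (camera adjusted p = 5.32e-05), and monocyte markers in 1 of 9 (alone 5), with a median of 3.18 (adjusted p = 0.0176). Astrocyte markers were more negative in 1 of 11 cases (alone 2), Slc1a3 by -0.74, with a median of -0.82 (adjusted p = 2.86e-05). Oligodendrocyte precursor markers had 0 of 6 genes called and a median of -1.06 (adjusted p = 0.0193). These 4 lists had adjusted p = 0.436 with an estimated correlation. Neutrophil markers deviated most in start Cre- replicate 2 and peak Cre+ replicate 3 (list means 2.65 and 3), and without the latter the median was 2.39 (adjusted p = 0.00369). Monocyte markers had a median of 1.10 without it and were not called without it or start Cre+ replicate 3 (up to 0.103). Precursor markers lost their call without start Cre- replicate 2 or 3, start Cre+ replicate 2, peak Cre- replicate 2 or peak Cre+ replicate 1 (up to 0.0947) or with GC content and length corrected (0.0524). Their median was -1.72 without start Cre- replicate 1, where the astrocyte median was -1.25. Mural markers were more negative in 4 of 5 cases both ways, with a median of -2.64 (adjusted p = 1.57e-07, adjusted p = 0.108 with an estimated correlation). Endothelial markers were more negative in 1 of 7 cases (alone 3), with a median of -1.53 (adjusted p = 0.00011, adjusted p = 0.202 with an estimated correlation), -2.43 without peak Cre+ replicate 2. MHC class II genes had 0 of 10 called (alone 1 more negative) and a median of -0.35 (adjusted p = 0.019, adjusted p = 0.468 with an estimated correlation). That call ended without start Cre- replicate 1, start Cre+ replicate 1 (median -0.09), peak Cre- replicate 3 or peak Cre+ replicate 2 (up to 0.18). The interaction count was 341 without start Cre- replicate 2 or start Cre+ replicate 2, and 400 and 415 without start Cre- replicate 3 and start Cre+ replicate 1. It was 436, 265 and 416 without peak Cre- replicates 1 and 2 and peak Cre+ replicate 3, and 1056 by DESeq2 and 996 by limma-voom.

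Demyelination was then compared with the naive state within each genotype. In Cre- mice 6309 genes differed, 3459 higher and 2850 lower. The matrix protein osteopontin, Spp1 (chromosome 5, 104435118 to 104441050), rose from 9.887 ± 1.29 to 4710 ± 1330 CPM (SD, n = 3), a log2 change of 8.90 ± 0.38 (SE, adjusted p = 3.99e-12). The growth factor Igf1 rose from 1.874 ± 0.665 to 321.5 ± 57 CPM (7.49 ± 0.3, adjusted p = 2.29e-13). The lysosomal glycoprotein gene Gpnmb rose by 8.56 ± 0.5 (adjusted p = 4.51e-10) and Ch25h, which makes an antiviral oxysterol, by 7.50 ± 0.3 (adjusted p = 1.27e-13). Among eligible genes the orphan receptor Gpr165 fell most (-2.81 ± 0.4, adjusted p = 2.82e-05). All 25 disease-associated genes rose both ways, Apoe by 6.04 and Itgax by 5.28. Their median was 3.55 (camera adjusted p = 7.62e-74, adjusted p = 0.000307 with an estimated correlation). Interferon genes rose in 29 of 30 cases both ways, Oas1a by 3.52, with a median of 2.16 (adjusted p = 3.8e-48). MHC class II genes rose in 7 of 10 cases both ways, Cd74 by 4.57, with a median of 1.67 (adjusted p = 2.56e-09). Homeostatic genes fell in 19 of 20 cases (20 adjusted over the list alone), Tmem119 by -1.70 and P2ry13 by -1.65, with a median of -0.83 (adjusted p = 9.04e-18).

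Also higher in demyelination in Cre- were lipid efflux genes (13 higher and 2 lower of 18, alone 14 and 2), growth factors (8 and 0 of 13, alone 9 and 0), MHC class I genes (11 and 0 of 14, alone 12 and 0), cytokines (13 and 1 of 17, alone 13 and 2) and border-associated macrophage markers (9 and 1 of 10 both ways). All 9 of these lists were called with an estimated correlation too. Cell cycle genes rose in 20 of 27 cases (21 adjusted over the list alone, and 1 lower), Cdk1 by 2.08, with a median of 1.22 (camera adjusted p = 2.4e-05, adjusted p = 0.515 with an estimated correlation). Lysosome genes (22 and 2 of 33 both ways, adjusted p = 0.0884 with an estimated correlation), monocyte markers (8 and 0 of 9 both ways, adjusted p = 0.0836 with an estimated correlation) and phagocytosis receptors (12 and 6 of 24 both ways, adjusted p = 0.148 with an estimated correlation) were called with the preset correlation alone.

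In Cre+ mice 9181 genes differed, 4626 higher and 4555 lower. Gpnmb (11.26 ± 0.63, adjusted p = 9.13e-11), Spp1 (9.28 ± 0.39, adjusted p = 1.11e-12) and Cst7 (8.93 ± 0.31, adjusted p = 8.73e-15) were among the highest eligible genes and Gpr165 was the lowest (-4.18). Of 15 lists called, 4 held with an estimated correlation, namely disease-associated, interferon, lipid efflux and growth factor genes. Cholesterol biosynthesis genes were 15 higher and 1 lower of 23 (16 and 2 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.0163, adjusted p = 0.486 with an estimated correlation). The miRNA machinery fell in 9 of 12 cases both ways, with a median of -0.47 (adjusted p = 0.0163, adjusted p = 0.0955 with an estimated correlation).

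Remyelination with tamoxifen at the start was compared with demyelination and with naive in Cre- mice. The pituitary hormone gene Gh, chosen after its values were seen, held at most 0.0387 CPM in naive and demyelination libraries and 5.84 to 157 CPM in every remyelination library. mt-Co2 held 0.154 to 0.7125 against 18.15 to 34.5 CPM, so state and library set cannot be told apart. Longer genes tended to be higher at the start (rho 0.50 against demyelination, 0.42 against naive). Against demyelination 9609 genes differed, 4628 higher and 4981 lower. Spp1 fell from 4710 ± 1330 to 136.7 ± 44.8 CPM (SD, n = 3), a log2 change of -5.11 ± 0.32 (SE, adjusted p = 4.24e-10). The lipid-release enzyme gene Lpl fell from 2295 ± 379 to 129.7 ± 30 CPM (-4.14 ± 0.21, adjusted p = 2.08e-12), Cst7 by -4.64 and Apoc1 by -6.23. Of the eligible genes mt-Co2 rose most (5.31 ± 0.23, adjusted p = 3.07e-15). Disease-associated genes fell in 24 of 25 cases both ways, Apoe by -3.23 and Cd63 by -2.46, with a median of -2.46 (camera adjusted p = 3.05e-36, adjusted p = 0.00753 with an estimated correlation). Lysosome genes fell in 26 of 33 cases (27 adjusted over the list alone), with a median of -0.88 (adjusted p = 2.04e-16), and lipid efflux genes in 12 of 18 (alone 13), with one of -0.97 (adjusted p = 1.39e-08). Both had adjusted p = 0.046 with an estimated correlation. Interferon genes fell in 27 of 30 cases (alone 28), with a median of -1.82 (adjusted p = 1.19e-17, adjusted p = 0.0986 with an estimated correlation). Of 13 lists called, the first 3 of these held.

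Against naive 9881 genes differed, 5062 higher and 4819 lower. P2ry12, a homeostatic receptor that senses nucleotides, fell from 12060 ± 1240 to 4225 ± 294 CPM (log2 -1.51 ± 0.15, adjusted p = 8.62e-09), and Gpr34 from 5611 ± 992 to 1925 ± 84.9 CPM (-1.54 ± 0.16, adjusted p = 2.28e-08). Apoe (2.82) and Igf1 (3.70) rose, and the gelatinase gene Mmp9 rose most of the eligible genes (6.58 ± 1.06, adjusted p = 5.88e-05). Border-associated macrophage markers rose in 10 of 10 cases both ways, with a median of 3.79 (camera adjusted p = 1.62e-19, adjusted p = 0.0136 with an estimated correlation). This was the only one of 10 called lists to hold.

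Last, peak against start tamoxifen in Cre- mice called 96 genes, all lower at the peak. Titles differ in style too, so timing and batch cannot be told apart. Spp1 fell from 136.7 ± 44.8 to 21.42 ± 9.18 CPM (SD, n = 3), a log2 change of -2.68 ± 0.3 (SE, adjusted p = 0.000606). The cytokine Il1b fell from 129 ± 63.3 to 23.43 ± 6.79 CPM (-2.46 ± 0.32, adjusted p = 0.00116) and the prostaglandin enzyme gene Ptgs2 by 2.39 ± 0.4 (adjusted p = 0.00583). Dissociation and immediate early genes fell in 12 of 16 cases (16 adjusted over the list alone), Fos by -1.60 and Zfp36 by -1.53. Their median was -1.17 (camera adjusted p = 3.64e-57, adjusted p = 0.00124 with an estimated correlation). Disease-associated genes fell in 7 of 25 cases (alone 13), with a median of -0.53 (adjusted p = 7.24e-23), and cytokines in 5 of 17 (alone 8), Cxcl2 by -1.94, with a median of -0.78 (adjusted p = 7.61e-18). Border-associated macrophage markers fell in 3 of 10 cases (alone 8), with a median of -0.77. These 3 lists had adjusted p = 0.0137 with an estimated correlation. Monocyte markers fell in 2 of 9 cases (alone 8), with a median of -2.58 (adjusted p = 0.0104 with an estimated correlation). Neutrophil markers had 0 of 12 genes called (alone 9 lower) and a median of -3.04 (adjusted p = 1.83e-11, adjusted p = 0.102 with an estimated correlation). The count was 32 without start Cre- replicate 2 and 33, 42 and 36 without peak Cre- replicates 1, 2 and 3.

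Seed-site tests asked whether transcripts with microglial miRNA sites rose in Cre+, as lost repression would have it. Among 13396 genes with a 3′ UTR searched, 11 of 21 expressed families shifted upward in naive microglia and 0 of 3 control families did (camera, adjusted p from 0.0288 to 0.0477). For miR-25/92 the median log2 change was 0.103 among genes with a site and -0.028 among others, but the mean difference at matched UTR length was 0.052. A control family of muscle miRNAs had medians of 0.050 and -0.028 (0.003 at matched length). None of the 11 was called with an estimated correlation (adjusted p = 0.223 with an estimated correlation at the lowest), among UTRs of at least 500 bases, or after correction for GC content and length. In the other 3 states 0 of 21 families were called.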

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

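Tests of a mislabelled sample, of few changed cells, and of GC content and gene length were chosen only after seeing the result. So were fits without low-Cx3cr1 libraries or with a lone Cre+ library, and slopes per library.

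Genotype effects differed between states by the interaction tests. Between demyelination and naive 2769 genes differed, and the effect in demyelination was shifted upward for disease-associated genes (median log2 difference 0.81), interferon genes (0.71), cytokines (1.19), cholesterol biosynthesis (0.51) and lysosome genes (0.35), and downward for TGF-beta signalling (-0.23), the miRNA machinery (-0.38) and let-7 targets (-0.36). None of these 8 lists was called with an estimated correlation (adjusted p = 0.0612 at the lowest). Between start and demyelination 657 genes differed, with shifts of -1.84 for cell cycle, -0.24 for phagocytosis and -0.34 for lysosome genes. None was called that way (adjusted p = 0.399 at the lowest). Between tamoxifen timings 662 genes differed, with shifts of 3.39 for cell cycle genes, 0.40 for p53 targets, 0.28 for the miRNA machinery, 0.40 for let-7 targets, -1.53 for endothelial and -2.64 for mural markers. Of these only the cell cycle list was called with an estimated correlation (adjusted p = 0.008, against 0.108 to 0.202 for the others).

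Library splits, 33 of 200 with the real one, were run for these 3 counts. For demyelination against naive, 2 of 33 splits gave at least as many genes as the real 2769, so chance was not excluded. The highest other, 3146, mixed the demyelination libraries but kept naive Cre+ and Cre- apart, so it still held the naive genotype effect and says little about chance alone. For start against demyelination 1 of 33 did, the real one with 657. Only the splits keeping demyelination Cre+ and Cre- apart (86, 114 and 148) bear on the difference, too few to exclude chance. For both timings 2 of 33 did, so chance was not excluded. The highest other, 874 against 662, mixed the start libraries but kept peak Cre+ and Cre- apart, so it likewise held the peak genotype effect.

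Few genes differed by genotype with tamoxifen at the start, 6 against 1612 to 4982 in the other states. Lower depth is argued against: with the naive and demyelination libraries thinned to 10.6 M counts, the mean of the start libraries, demyelination still gave 1391 genes and naive 4279. A mislabelled sample is argued against by Cx3cr1: the highest Cre+ library held 59.27% of the Cre- mean and the lowest Cre- library 89.54%. That few sorted cells carried the changes of the other states stays open. Over 401 genes called alike there, the slope of start effects on theirs was -0.09 (-0.02, -0.01 and -0.06 in single Cre+ libraries). Such a slope restates the low count, so it cannot decide. Start medians were -0.03 for the higher genes (1.15 elsewhere) and -0.14 for the lower (-0.8). Some effects were shared: 5 of the 6 genes were also higher in naive. Start and naive effects had r 0.07, and 0.28 at a mean log2 CPM of at least 4 (0.16 with GC content and length corrected). At that level r was -0.07 with demyelination and 0.07 with the peak. Cell turnover or a weaker response at this time were not tested.

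Most genotype differences were in the naive state. A trend with GC content or gene length as the whole cause is argued against: with it removed 4806 genes were called, although only 3681 of them were among the 4982, so part of that list depends on it. A single library is argued against as well, since leaving out each in turn gave at least 3734 genes. A biological difference between resting and challenged microglia as the cause was not tested.

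Cx3cr1 was far below the level of other Cre+ libraries in 3 of 12. A lower share of microglia is argued against: 20 other homeostatic genes had medians of 0.10, 0.15 and 0.03 against the Cre- mean in these libraries, none below 0. Whether creERT2 sat on both alleles in these animals, which could remove Cx3cr1 RNA altogether, cannot be told apart from other causes. The test asked whether a larger share of genes near Cx3cr1 changed over 2-fold in these libraries, relative to all genes, than in any other Cre+ library of the state. It did in 2 of the 3: 2.31 times in naive Cre+ replicate 1 (2.26 and 1.94 in the others) and 3.58 times in demyelination Cre+ replicate 3 (1.89 in replicate 2). Demyelination Cre+ replicate 1 had 0.71 times, which meets the bound written against this explanation. These shares rest on 1 to 9 of 58 genes, so the explanation stays open. In demyelination the pattern matters for the count: a fit with replicate 1 or 3 as the lone Cre+ library gave 1736 or 545 genes, and one with replicate 2 gave 6. Leaving out the low naive library as well gave 81, of which 78 were among the 1612. At an unadjusted p below 0.05 these fits gave 1244 and 1299 genes, and in each 1608 of the 1612 kept their sign, at a median of 0.68 times the full change. By contrast, in naive the lone-library fits gave 2371 for the low library and 1846 and 2559 for the others.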

How the results depend on the processing

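The GC and length correction and the fits without low-Cx3cr1 libraries were chosen after seeing the data. Counts within 1.5 times the reported one are taken as unchanged here; causes were not tested except where stated.

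With DESeq2 size factors in edgeR, a filter of 1 CPM and the replicate block, all 12 gene counts were unchanged. The split by direction moved with DESeq2 size factors in demyelination (1247 higher, 467 lower, against 1001 and 611) and in the demyelination by naive interaction (1794 and 1069, against 1401 and 1368). The naive majority turned from 2580 higher and 2402 lower to 2339 and 2663 with these factors, 2467 and 2847 with DESeq2, 2239 and 2567 with GC and length corrected and 2071 and 2114 without low-Cx3cr1 libraries, so neither direction prevailed. That of start minus demyelination (4628 and 4981) turned to 4907 and 4712, 4896 and 4656, and 4967 and 3675 in the first 3 of these.

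With GC and length corrected 21 of 22 counts were unchanged, but not the genes behind them: calls kept were 3681 of 4982 in naive, 1728 of 2769 and 430 of 657 in the first interactions, 7173 of 9181 for demyelination minus naive in Cre+, and 6501 of 9609 and 7378 of 9881 for start minus demyelination and naive. Directions became 1229 higher and 1039 lower at the peak (1228 and 707), 221 and 356 in the start interaction (140 and 517), 401 and 274 for timing (505 and 157), and 2803 and 4182 in Cre- and 3911 and 5367 in Cre+ for demyelination minus naive (3459 and 2850, 4626 and 4555).

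A 2-fold minimum lowers counts by construction: naive 1399, demyelination 487, start 2, peak 570, interactions 928, 192 and 341, demyelination minus naive 2277 (Cre-) and 3878 (Cre+), start minus demyelination 4321 and minus naive 3791. Without a filter the start gave 81 genes (37 higher, 44 lower), its interaction with demyelination 1026 and the timing comparison in Cre- 244. With only the groups compared these were 40, 1062 and 180. DESeq2 gave 76 genes at the start (11 higher, 65 lower), 1439 and 1056 in the start and timing interactions and 217 for timing in Cre-. Limma-voom gave 3260 in demyelination, 26 at the start, 1549 and 996 in those interactions and 56 for timing; the cause was not tested. Without low-Cx3cr1 libraries, and so with fewer libraries, demyelination gave 81, its interaction with naive 1631 and that with the start 43.

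Leaving out each library in turn gave 3734 to 4742 genes in naive, 417 to 2114 in demyelination, 1 to 6 at the start, 883 to 2176 at the peak, 1882 to 3006, 97 to 1158 and 265 to 944 in the 3 interactions, 5013 to 6251 and 8296 to 8566 for demyelination minus naive in Cre- and Cre+, 8550 to 8952 and 8780 to 9472 for start minus demyelination and minus naive, and 32 to 112 for timing. Lists called ranged over 10 to 11, 8 to 12, 7 to 12, 10 to 13, 7 to 11, 8 to 13, 10 to 14, 13 to 14, 15 to 16, 12 to 14, 8 to 16 and 13 to 15 in the same order.

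With an estimated correlation, which widens each list's error, the lists called fell from 11 to 1 (naive), 10 to 0 (demyelination), 12 to 0 (start), 10 to 1 (peak), 8 to 0, 9 to 0 and 13 to 1 (interactions), 15 to 4 (demyelination minus naive in Cre+), 13 to 3 and 10 to 1 (start minus demyelination and naive) and 15 to 6 (timing), and stayed at 9 of 13 in Cre-. Fry, which compares no list with other genes, called 0 at the start, 3 and 6 in the last 2 interactions, 26, 20 and 22 in the Cre+ and start state comparisons and 9 for timing. Shared calls at a mean log2 CPM of at least 4, with fewer genes, were 334, 765 and 323 for naive with demyelination, naive with peak and demyelination with peak (621, 1181 and 569 reported). Naive seed-site calls (11) ranged from 0 to 13.

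Of 186 named gene values 169 were called; none reversed or lost its call with DESeq2 (179 compared), 4 gained one, and 23 called values fell short without at least 1 library. Genes changed 1.5-fold, drawn from those with a log2 CPM above 2, were recovered in 49.3% of simulated cases at the depth of the start state. Changes of that size can be missed there. A sex covariate was not run, since all libraries were male.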

Other observations

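Values per library below were chosen after seeing the data, while the splits were planned.

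The cell cycle and disease-associated programmes did not move together in single naive libraries. Cell cycle genes had mean log2 deviations of -0.74, -0.64 and -0.49 in Cre- and of 0.78 and 0.67 in Cre+ replicates 2 and 3, but -0.72 in Cre+ replicate 1, the low-Cx3cr1 library. Disease-associated genes lay at -1.88, -1.85 and -1.89 in all 3 Cre+ libraries and between -1.28 and -1.02 in Cre-. In demyelination, cell cycle deviations were 1.67, 1.61 and 1.56 in Cre+, low-Cx3cr1 libraries included, and 0.32 to 0.52 in Cre-. With tamoxifen at the peak they were 1.34, 1.04 and 1.31 in Cre+ and -1.21 to -1.03 in Cre-.

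Neutrophil markers were highest in a pair of libraries. S100a8, an alarmin of neutrophils, held 1246 CPM in start Cre- replicate 2 and 1301 CPM in peak Cre+ replicate 3, and 50.87 to 139.7 CPM in the other 5 peak libraries. Start Cre- replicate 3 held 521.8 CPM, and demyelination libraries 360.7 to 477.2 CPM in Cre+ and 64.73 to 241.1 CPM in Cre-.

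The 2-group comparisons have 10 splits of 6 libraries each, too few for a share under 0.05. The real split was the highest (1 of 10) in each. The naive comparison gave 4982 genes and at most 78 in another split, demyelination 1612 and 7, the start 6 and 0, and the peak 1935 and 1. At the peak residuals correlated best within replicate numbers, although no label states a pairing. There the 3 other splits that part all libraries of equal number gave 0 genes, and the 6 that part 1 such pair at most 1. Demyelination minus naive gave 6309 and 0 in Cre- and 9181 and 3 in Cre+, start minus demyelination 9609 and 0, start minus naive 9881 and 0, and the timing comparison 96 and 0.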
